A study of Homo sapiens with 18 samples.

How the data were processed

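RNA with a poly(A) tail was sequenced from 2 human keratinocyte lines, HaCaT from skin and TIGK from gingiva, kept for 10 minutes at -25°C, 37°C or 60°C and lysed straight afterwards. There were 3 libraries in each of 6 groups, 18 in all. Per the labels, a sequencing company prepared the libraries and mapped the reads to hg38 with HISAT2 2.0.5. StringTie 1.3.3b was named for assembly and featureCounts 1.5.0-p3 for counting reads per gene. The gene annotation release and the strand setting were not stated. The deposited count table holds whole read counts for 58735 genes in the 18 libraries, with no normalisation. It also holds each gene's length in bases, which the deposited file gives as a column of its own (another kind of value, used only to describe the file).

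The authors also deposited 7 tables of genes they called, 1 for each treatment against 37°C in each line and 1 for HaCaT against TIGK at each temperature. The column names are those of a DESeq2 result, although the labels name no tool. In these tables the authors give a log2 fold change with its standard error, a test score named stat, and a signal named baseMean, the mean of the scaled counts. The authors also give a p-value and an adjusted p-value, and the genes listed in the 7 tables all have an adjusted p-value of at most 0.01. In the table of TIGK at 60°C, gene symbols and Ensembl IDs did not belong together for 633 of 1172 genes. Where they differed, the authors' fold changes followed the symbols (r across genes with the fold changes computed here 0.997, against 0.474 by ID), so that table was joined by symbol. Its baseMean values followed the IDs.

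Library totals ran from 12003989 to 27203463 counts. No gene was counted in any library for 20848 genes. Genes were kept with the filterByExpr function of edgeR 4.0.16 (R 4.3.3), which left 19038. Libraries were scaled with TMM factors. A quasi-likelihood model with robust spread and 1 mean per group was fitted to all 18 libraries together, with 12 residual degrees of freedom. Tests were two-sided. P-values were adjusted with the Benjamini-Hochberg method over the genes tested in each comparison, and an adjusted p under 0.05 was taken as past the test. The standard error of a log2 fold change was taken as its size over the square root of its F statistic. Levels are CPM, counts per scaled library total in the usual unit, as means with SD over the 3 libraries of a group.

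There were 9 comparisons chosen before the data were examined. They were -25°C and 60°C against 37°C in each line, HaCaT against TIGK at each temperature, and the difference between the lines' changes (HaCaT change minus TIGK change) at -25°C and at 60°C. The direct comparison of 60°C with -25°C in each line was added after seeing the data. The labels do not say whether the replicates were separate cultures, passages or days, so p-values measure the spread among these libraries. That spread is estimated per gene over both lines, although the biological coefficient of variation was 6.37% in HaCaT and 13.6% in TIGK fitted alone. The TIGK value includes 37°C replicate 3, which stood apart from its replicates. Standard errors and p-values from the joint spread tend to be too large for HaCaT and, in comparisons with 37°C, too small for TIGK. This also affects the counts of list members. For 60°C against -25°C in TIGK the joint fit gave 126 genes and the compared libraries alone 255, so the tendency is not seen there. Replicate numbers did not pair libraries across groups: of 45 pairs of libraries with the same number, 0 had a correlation of residuals across genes above 0.1, and 16 matched their own number best.

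The 27 gene lists were fixed before the data were examined, and 646 of their genes were tested in at least 1 list. They were heat shock proteins and co-chaperones, immediate early genes, inflammatory genes of the NF-kappaB type, the unfolded protein and integrated stress responses, cold-inducible RNA-binding proteins, temperature-sensing channels with calcium-entry partners, antioxidant genes, p53 and apoptosis genes, lytic cell death machinery, the genes of the mitochondrial genome, nuclear genes of the respiratory chain, ribosomal proteins, and replication-dependent histones. For keratinocytes they were cornified-layer differentiation, basal layer and adhesion, wound keratins with antimicrobial proteins, oral epithelial genes and HOX genes. The others were the cell cycle, interferon-stimulated genes, sterol synthesis and uptake, osmotic stress, and mesenchymal genes. Markers of fibroblasts, of melanocytes, of leukocytes, and of endothelial with Merkel cells stood for cells that a keratinocyte culture should lack. Lists of at least 5 tested genes were tested against all other genes with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation. The leukocyte list had 3 tested genes and is given as counts. Members past the test were counted over all genes tested and again with p-values adjusted over the list alone.

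The genes named in the text were chosen by a rule fixed beforehand. For each comparison of 2 groups these were the 10 largest rises and the 10 largest falls past the test among protein-coding genes with a mean of at least 5 CPM in the higher group and all 3 libraries of one group above all 3 of the other. Chance alone gives such a separation in 10% of genes. For the difference between the lines, 5 genes each way were taken. Up to 4 members of each list with the smallest p-values were added, and a fixed set was always read: HSPA1A, HSPA1B, DNAJB1, HSPH1, FOS, EGR1, ATF3, JUN, CXCL8, IL1A, IL1B, CIRBP, RBM3, TRPV3, TRPM8, KRT1, KRT10, KRT5, KRT14, KRT13, KRT4, TERT and PITX1. Some genes that the rule takes are not reported here. From these, genes whose calls held in every setting were preferred as examples after their values were seen. Genes of the Y chromosome and XIST were not named. Spreadsheet damage had turned 27 symbols into dates, and 177 symbols were shared by more than 1 gene, so genes were followed by Ensembl ID.

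A fold against a group with 0 counts is given as a lower limit, computed with 3 counts over that group's libraries. With 1 to 3 counts the ratio is given with a 95% interval. Binomial intervals of shares of genes are exact (Clopper-Pearson). These limits and intervals cover counting error only. The overlap of called genes was tested with a one-sided Fisher exact test over the genes tested. Correlations across genes and the p-values of these overlaps are descriptive, since genes are not independent replicates. A random draw of 100 data sets without any treatment effect, simulated from the fitted spread, gave the correlation that 2 comparisons have merely because they share their 37°C libraries.

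The alternatives were relative log expression factors, library size alone, DESeq2 1.42.0, no filter, a filter of 1 CPM in 3 libraries, only the compared libraries, a term for the replicate number, leaving out each library in turn, a log2 fold change of at least 1 as well, protein-coding genes only, and the estimated correlation. Leaving out 3 doubted libraries together, and DESeq2 on only the compared libraries, were added after seeing the data. The 3 were the -25°C library with the fewest genes at exactly 1 count in each line (HaCaT replicate 1, TIGK replicate 2) and TIGK 37°C replicate 3. Counts of the same size were simulated with the spread of the fit to all 18 libraries. The changed genes were drawn from those averaging above 1 CPM. From these counts edgeR called 58% of genes changed 1.5-fold, 74% of those changed 2-fold, 96% at 4-fold and 100% at 8-fold. Of its calls 3.89% were unchanged genes, and it made 0 calls where nothing had changed. DESeq2 called 64%, 80%, 96% and 100%, with 7.11% unchanged genes among its calls. Sequence-level questions such as splicing were left out, since the deposited files hold gene counts only.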

Results

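Poly(A) RNA was counted per gene in HaCaT, a spontaneously immortalised skin keratinocyte line, and in TIGK, a gingival keratinocyte line immortalised with telomerase. Cells stayed for 10 minutes at 37°C, the baseline, or were placed at -25°C or 60°C for 10 minutes, and RNA was extracted directly afterwards. Each of the 6 groups had 3 libraries. The title of the series asks whether oral and skin keratinocytes respond differently to temperature.

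The HaCaT libraries held 27203463, 22722969 and 24369188 counts at 37°C, 23190702, 21584065 and 19940006 at -25°C and 19507986, 22107829 and 20758392 at 60°C (replicates 1, 2 and 3 in turn). The TIGK libraries held 18705539, 24406484 and 22229359 counts at 37°C, 21611029, 24187577 and 12003989 at -25°C and 20576395, 21882655 and 19854216 at 60°C. The lines were the largest difference among the libraries: the first principal component held 75.6% of the variance and separated them. The spread between replicates differed between the lines, with a biological coefficient of variation of 6.37% in HaCaT and 13.6% in TIGK fitted alone, and 10.8% in the joint fit. The TIGK value includes 37°C replicate 3 and was not computed without it. Chi-square per degree of freedom was 55.8 and 62.3 between that library and its replicates. It ran from 3.56 to 12.4 for the other TIGK replicate pairs and from 3.83 to 5.72 for HaCaT. Against 37°C, the joint fit called more genes in TIGK and fewer in HaCaT than the 6 libraries of each comparison did by themselves. For 60°C against -25°C it called fewer in TIGK too (126 against 255). Numbers of called genes are therefore not compared between the lines.

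Several libraries stood apart, and these facts accompany every gene group below. By group mean, treated libraries detected fewer genes than 37°C libraries in both lines. At the smallest library's depth a mean of 24009 ± 405 genes (SD, n = 3) was expected in HaCaT at 37°C, 22609 ± 481 at -25°C and 22789 ± 154 at 60°C. In TIGK the means were 24386 ± 719, 23220 ± 779 and 23849 ± 118. Single TIGK libraries overlapped: 37°C replicate 3 had 23574, below the 60°C libraries (23942, 23716 and 23890) and -25°C replicate 3 (24037). The 37°C replicates 1 and 2 had 24642 and 24942, above all treated TIGK libraries. HaCaT -25°C replicate 1 and TIGK -25°C replicate 2 had the fewest genes with exactly 1 count, 1061 and 1203. TIGK 37°C replicate 3 differed from its replicates far beyond counting error: chi-square per degree of freedom was 55.8 and 62.3 against replicates 1 and 2, and 3.56 between those 2. These 3 are called the doubted libraries here. The share of counts on mitochondrial ribosomal RNA was 0.577% ± 0.106 in TIGK at 37°C, 0.326% ± 0.01 at -25°C and 0.25% ± 0.006 at 60°C. In HaCaT it was 1.86% ± 0.055, 1.99% ± 0.045 and 2.14% ± 0.022.

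**Figure D1:**
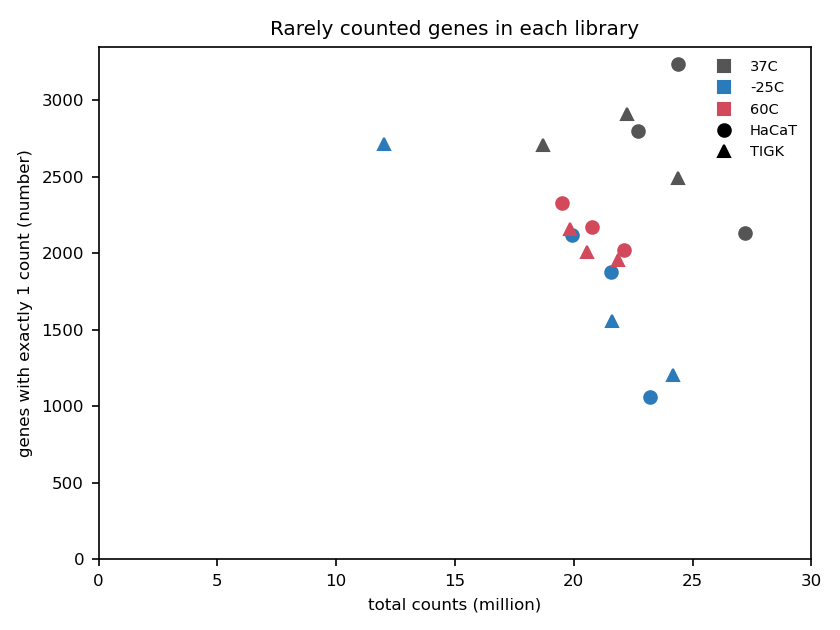
Number of genes with exactly 1 count (vertical axis) against the total count of each of the 18 libraries (horizontal axis, as labelled), with circles for HaCaT, triangles for TIGK and colours for temperature. HaCaT -25°C replicate 1 and TIGK -25°C replicate 2 lie lowest, at 1061 and 1203 genes, while the 6 libraries at 37°C lie between 2130 and 3240.

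In HaCaT at -25°C, CXCL14, a chemokine of epithelia, rose by 1.74 ± 0.24 on the log2 scale (SE, n = 3 in each group), from 35.0 ± 1.91 to 117 ± 13.7 CPM (SD). MMP13, a collagenase, rose by 2.04 ± 0.18. FN1, which encodes fibronectin, fell by 1.62 ± 0.19, from 3465 ± 148 to 1130 ± 25 CPM. POSTN, which encodes the matrix protein periostin, fell by 3.88 ± 0.38. In hg38 CXCL14 (ENSG00000145824) lies on chromosome 5 from 135570679 to 135579279, FN1 (ENSG00000115414) on chromosome 2 from 215360440 to 215436172, and HSPA1A (ENSG00000204389) on chromosome 6 from 31815464 to 31817946. HSPA1A, the main heat-inducible HSP70 gene, stood at 139 ± 11.1 against 153 ± 7.32 CPM and did not pass the test (log2 difference -0.13 ± 0.09, adjusted p = 0.42).

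Of 24 genes of the unfolded protein and integrated stress responses, 10 rose and 1 fell (14 and 1 adjusted over the list alone). HSPA5, the main chaperone of the endoplasmic reticulum, rose by 0.39 ± 0.06 and HERPUD1, a part of the machinery that removes misfolded proteins there, by 0.48 ± 0.07. The list lay above other genes (adjusted p = 5e-07), with adjusted p = 0.143 with an estimated correlation. Of 28 heat shock genes, 11 fell and 3 rose (13 and 3 adjusted over the list alone; adjusted p = 0.00305, and adjusted p = 0.429 with an estimated correlation). HSPH1, a co-chaperone of HSP70, fell by 0.39 ± 0.07 and DNAJA1 by 0.54 ± 0.09, whereas the small heat shock gene HSPB8 rose by 1.17 ± 0.15. Of 39 immediate early genes, 7 rose (11 adjusted over the list alone; adjusted p = 6.1e-06, and adjusted p = 0.143 with an estimated correlation). JUNB rose by 0.74 ± 0.07 and ID1 rose from 26.1 ± 0.715 to 73.5 ± 14.5 CPM. EGR1 stood higher by 0.97 ± 0.30 without passing the test (adjusted p = 0.0577). With the doubted libraries left out, 14 stress response genes rose, 13 heat shock genes fell and 10 immediate early genes rose.

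Of 14 wound keratins and antimicrobial genes, 4 fell and 1 rose, the same counts when adjusted over the list alone (median -0.78; adjusted p = 0.00305, and adjusted p = 0.219 with an estimated correlation). KRT6B, a keratin of wounded epidermis, fell by 2.17 ± 0.37. Of 32 cornified-layer genes, 3 fell and 2 rose (7 and 2 adjusted over the list alone; adjusted p = 0.27). TGM1, the enzyme that crosslinks the cornified envelope, rose by 1.06 ± 0.08, while FLG, which encodes filaggrin, fell by 0.53 ± 0.08. Of 31 cell cycle genes, 5 fell (7 adjusted over the list alone), TPX2 by 0.32 ± 0.06, with adjusted p = 0.00305 and adjusted p = 0.429 with an estimated correlation. Sterol genes rose in 4 of 20 and fell in 1 (8 and 2 adjusted over the list alone; adjusted p = 0.00305, and adjusted p = 0.316 with an estimated correlation). Ribosomal protein genes rose in 3 of 80 and respiratory chain genes in 5 of 82 (2 and 2 adjusted over the list alone), with adjusted p = 0.00305 and 0.0217, and adjusted p = 0.776 for both with an estimated correlation. In the fit without the doubted libraries, 28 ribosomal protein genes rose and 2 fell, 20 respiratory chain genes rose and 1 fell, 10 cell cycle genes fell and 9 sterol genes rose. Antioxidant genes rose in 8 of 25 and fell in 2 (10 and 4 adjusted over the list alone; adjusted p = 0.039, adjusted p = 0.509 with an estimated correlation, and 0.0583 with a term for the replicate block). Mesenchymal genes fell in 6 of 18 and rose in 2 (7 and 3 adjusted over the list alone; adjusted p = 0.0517). The other lists had adjusted p from 0.274 to 0.962. Among them were p53 and apoptosis genes (3 higher and 2 lower of 25), lytic death genes (4 and 2 of 18), temperature-sensing channels (1 and 1 of 9) and interferon-stimulated genes (1 and 1 of 26).

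The test called 1985 genes in HaCaT at -25°C, 1017 higher and 968 lower, of which 274 changed at least 2-fold. The number was 4252 with only the 6 compared libraries, 3615 with DESeq2 on those and 3201 without the doubted libraries. It was 1243, 1108 and 1242 without HaCaT 37°C replicate 1, 2 or 3, and 1166 and 1282 without HaCaT -25°C replicate 1 or 3.

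In HaCaT at 60°C, KRT1, the keratin of the suprabasal epidermis, fell by 2.41 ± 0.31, from 156 ± 65.6 to 29.3 ± 5.7 CPM. KRT1 (ENSG00000167768) lies on chromosome 12 from 52674736 to 52680407. DSG1, a desmosomal cadherin, fell by 2.87 ± 0.39 and FLG by 0.94 ± 0.08. FN1 fell by 1.73 ± 0.19, to 1042 ± 12.2 CPM, POSTN fell by 3.70 ± 0.37, and MMP13 rose by 2.17 ± 0.18. HSPA1A stood at 145 ± 4.65 against 153 ± 7.32 CPM (log2 difference -0.07 ± 0.09, adjusted p = 0.643).

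Of 32 cornified-layer genes, 10 fell and 1, TGM1 by 0.76 ± 0.08, rose (16 and 2 adjusted over the list alone; median -0.55; adjusted p = 0.000603, and adjusted p = 0.0635 with an estimated correlation). Wound keratins and antimicrobial genes fell in 5 of 14 and rose in 1 (6 and 1 adjusted over the list alone; median -1.29; adjusted p = 0.00109, and adjusted p = 0.106 with an estimated correlation). KRT16 fell by 1.51 ± 0.21. Stress response genes rose in 16 of 24 (16 higher and 1 lower adjusted over the list alone; adjusted p = 2.14e-07, and adjusted p = 0.0635 with an estimated correlation), PDIA4, an oxidoreductase of the endoplasmic reticulum, by 0.51 ± 0.06 and HSPA5 by 0.48 ± 0.06. Ribosomal protein genes rose in 21 of 80 (34 adjusted over the list alone; adjusted p = 5.98e-10), RPLP1 by 0.58 ± 0.11, and respiratory chain genes in 21 of 82 (24 adjusted over the list alone; adjusted p = 6.5e-08), NDUFV1 by 0.43 ± 0.06. Both had adjusted p = 0.44 with an estimated correlation. Osmotic stress genes fell in 5 of 11 and rose in 1, the same adjusted over the list alone (adjusted p = 0.00109, and adjusted p = 0.0635 with an estimated correlation). SLC5A3, an inositol transporter, fell by 0.85 ± 0.08 and AQP3, a water and glycerol channel, by 0.78 ± 0.1. In a fit that left out the doubted libraries, 16 of 33 cornified-layer genes fell, 62 ribosomal protein genes and 46 respiratory chain genes rose, and 7 osmotic genes fell.

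Immediate early genes rose in 10 of 39 and fell in 1 (13 and 2 adjusted over the list alone; adjusted p = 0.00109, and adjusted p = 0.181 with an estimated correlation), JUNB by 0.68 ± 0.07. Sterol genes rose in 8 of 20 and fell in 2 (9 and 2 adjusted over the list alone; adjusted p = 0.00195, and adjusted p = 0.181 with an estimated correlation). Antioxidant genes rose in 9 of 25 and fell in 4 (10 and 5 adjusted over the list alone; adjusted p = 0.0229, and adjusted p = 0.44 with an estimated correlation), NQO1 by 0.72 ± 0.11. Mesenchymal genes fell in 5 of 18 and rose in 2 (7 and 2 adjusted over the list alone; adjusted p = 0.0313, and adjusted p = 0.152 with an estimated correlation). Heat shock genes fell in 9 of 28 and rose in 3 without the list passing its test (10 and 3 adjusted over the list alone; adjusted p = 0.0932). HSPH1 fell by 0.42 ± 0.07 and HSPB8 rose by 1.26 ± 0.15. Cold-inducible genes rose in 3 of 9 and fell in 1 (adjusted p = 0.271; the median and the test were positive and the mean negative). CIRBP, a cold-inducible RNA-binding protein, rose by 0.28 ± 0.07. The test called 3672 genes, 1811 higher and 1861 lower, 453 of them at least 2-fold. With only the compared libraries the number was 6158, and without the doubted libraries 5786.

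In TIGK at -25°C, KRT1 rose by 3.26 ± 0.35, from 8.64 ± 2.26 to 82.1 ± 10.4 CPM, and SPRR1B, a precursor of the cornified envelope, by 2.33 ± 0.29, from 5.21 ± 2.68 to 26.2 ± 2 CPM. SPRR1B (ENSG00000169469) lies on chromosome 1 from 153031202 to 153032900. CXCL14 rose by 3.77 ± 0.25, from 51.4 ± 1.66 to 700.5 ± 137 CPM. EGR1, an immediate early transcription factor, rose by 2.28 ± 0.33 and MYC by 1.29 ± 0.09. FN1 fell by 1.87 ± 0.19, from 797 ± 277 to 219 ± 25.4 CPM, and COL8A1, a chain of collagen VIII, fell by 2.37 ± 0.18.

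Of 32 cornified-layer genes, 19 rose, as many as when adjusted over the list alone, with a median of 1.25 (adjusted p = 8.33e-20, and adjusted p = 1.21e-05 with an estimated correlation). Basal layer and adhesion genes rose in 7 of 20 (adjusted p = 2.57e-06, and adjusted p = 0.0118 with an estimated correlation), KRT14, the basal keratin, by 0.94 ± 0.1 and KRT15 by 1.00 ± 0.1. Wound keratins and antimicrobial genes rose in 6 of 14 (median 0.95; adjusted p = 5.85e-07, and adjusted p = 0.0106 with an estimated correlation), KRT16 by 1.70 ± 0.21. Immediate early genes rose in 17 of 39 and fell in 1 (19 and 1 adjusted over the list alone; adjusted p = 6.68e-14, and adjusted p = 0.00684 with an estimated correlation). FOS, JUN and ATF3 did not pass (log2 differences 0.20 ± 0.13, 0.08 ± 0.07 and 0.01 ± 0.17). Heat shock genes fell in 8 of 28 and rose in 4 (11 and 4 adjusted over the list alone; adjusted p = 0.36). HSPA1B fell by 0.51 ± 0.08, while the small heat shock genes CRYAB and HSPB1 rose by 1.39 ± 0.13 and 0.64 ± 0.08. HSPA1A fell by 0.39 ± 0.09 (adjusted p = 0.00504), with adjusted p = 0.101 when only the compared libraries were fitted and 0.0724 with DESeq2 on those. Inflammatory genes rose in 6 of 23 and fell in 1 (adjusted p = 0.204; the median was positive and the mean negative). With the doubted libraries left out, 17 of 33 cornified-layer genes, 9 basal genes, 5 wound genes and 13 immediate early genes rose.

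The test called 3139 genes in TIGK at -25°C, 1485 higher and 1654 lower, of which 392 changed at least 2-fold. With only the compared libraries the number was 886, and with DESeq2 on those 1182.

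In TIGK at 60°C, KRT1 rose by 2.87 ± 0.35, to 62.7 ± 7.45 CPM, SPRR1B by 2.04 ± 0.29, to 21.4 ± 2.56 CPM, and KLK10, a secreted protease of the kallikrein family, by 2.16 ± 0.1. CXCL14 rose by 3.54 ± 0.25, to 598 ± 228 CPM, and EGR1 by 2.04 ± 0.33. FN1 fell by 1.77 ± 0.19, to 234 ± 14.5 CPM, and PXDN, an enzyme that crosslinks collagen IV, fell by 2.79 ± 0.18. HSPA1A fell by 0.45 ± 0.09, from 81.2 ± 9.12 to 59.2 ± 6.5 CPM, and HSPA8, the constitutive HSP70 gene, by 0.67 ± 0.09.

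Of 32 cornified-layer genes, 19 rose (21 adjusted over the list alone), with a median of 1.12 (adjusted p = 1.23e-13, and adjusted p = 0.000128 with an estimated correlation). Wound keratins and antimicrobial genes rose in 5 of 14 (7 adjusted over the list alone), KRT17 by 0.91 ± 0.07, and basal genes rose in 7 of 20 and fell in 2 (10 and 2 adjusted over the list alone), KRT14 by 0.77 ± 0.1. Both lists had adjusted p = 0.000266, and adjusted p = 0.0497 with an estimated correlation. Immediate early genes rose in 14 of 39 and fell in 2 (adjusted p = 1.11e-06, and adjusted p = 0.0497 with an estimated correlation), MYC by 1.12 ± 0.09. Of 28 heat shock genes, 11 fell and 2 rose (12 and 2 adjusted over the list alone; adjusted p = 0.0403, and adjusted p = 0.673 with an estimated correlation), CRYAB by a rise of 1.29 ± 0.13. The heat shock list had adjusted p = 0.153 with only the compared libraries, 0.0993 without the doubted libraries and 0.0556 with a term for the replicate block. Temperature-sensing channels and calcium-entry partners rose in 3 of 9 (4 adjusted over the list alone), ORAI1 by 0.56 ± 0.1, with adjusted p = 0.0256 and adjusted p = 0.493 with an estimated correlation. Of 13 genes of the mitochondrial genome, 3 fell, MT-ND3 by 0.68 ± 0.1, with adjusted p = 0.0256 and adjusted p = 0.673 with an estimated correlation. All 13 fell in the fit that left out the doubted libraries (adjusted p = 2.62e-19 at the preset correlation). An estimated correlation, 0.559 for this list with all libraries, was not applied to that fit. TIGK 37°C replicate 3, left out there, had 4.212% of its counts on the mitochondrial genome. Replicates 1 and 2 had 5.592% and 5.411%, and the 60°C libraries 3.996%, 4.511% and 4.268%. The channel and mitochondrial lists both had adjusted p = 0.0746 with only the compared libraries, and the channels 0.0864 without the doubted libraries. Stress response genes fell in 3 of 24 (adjusted p = 0.419). When the doubted libraries were left out, 15 of 33 cornified-layer genes, 9 basal genes, 5 wound genes and 12 immediate early genes rose. The test called 3318 genes, 1696 higher and 1622 lower, of which 496 changed at least 2-fold, and 1294 with only the compared libraries or 1682 with DESeq2 on those.

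**Figure D2:**
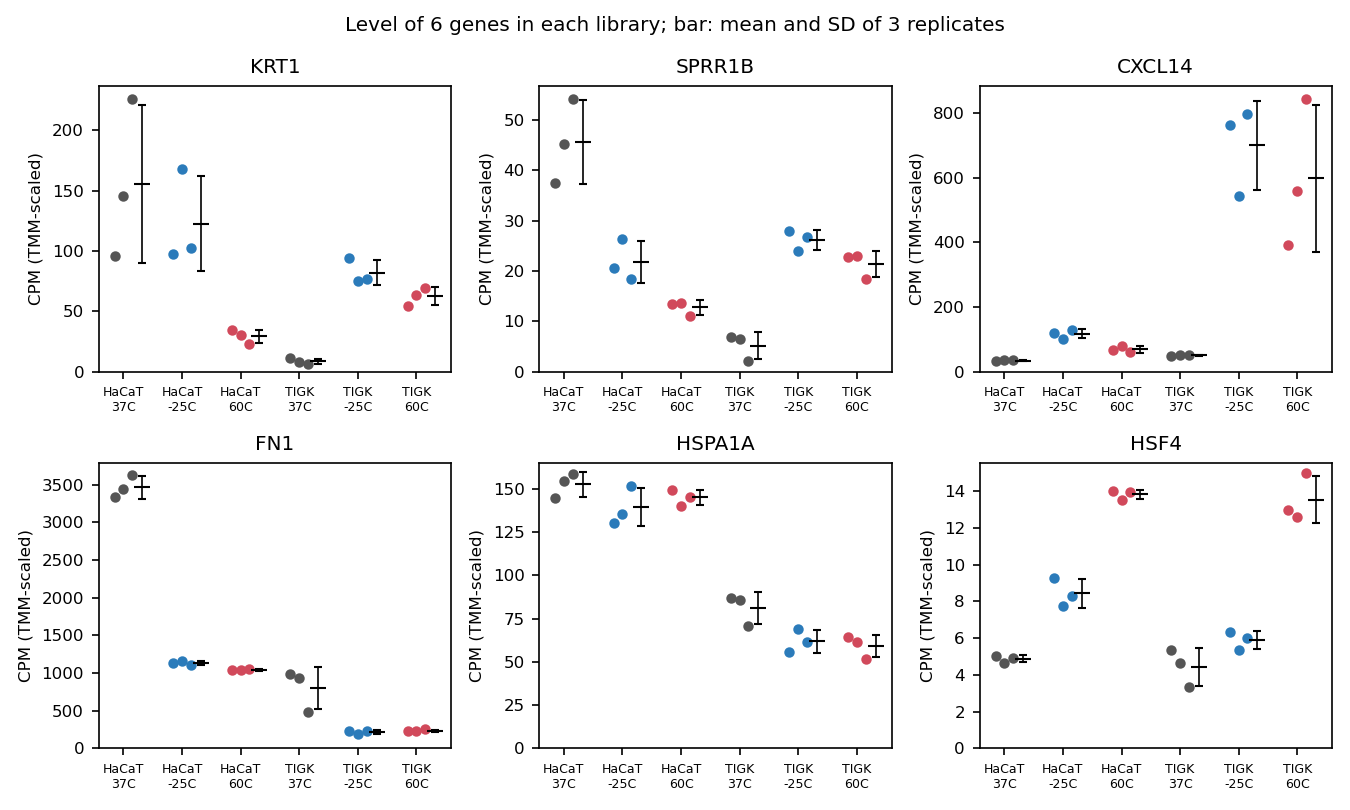
CPM of KRT1, SPRR1B, CXCL14, FN1, HSPA1A and HSF4 in each library (points), with the mean and SD of each group of 3 libraries. KRT1 falls from 156 to 29.3 CPM in HaCaT at 60°C and rises from 8.64 to 62.7 CPM in TIGK, while FN1 falls under both treatments in both lines.

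The treatments were opposite in temperature but overlapped in the genes called. In HaCaT 1599 genes changed in the same direction at -25°C and 60°C, 840 higher and 759 lower, and 1 gene in opposite directions. Independent calls would share 191.4. In TIGK 2083 genes were shared, 1015 higher and 1068 lower, with 4 opposite and 273.2 for independent calls. Those in opposite directions, named after their values were seen, were GABRE in HaCaT and MIR22HG, MIR222HG, CCDC18 and ZNF808 in TIGK. Both treatments were compared with the same 37°C libraries, which alone gives a correlation: across genes r was 0.579 (rho 0.638) in HaCaT and 0.63 (rho 0.657) in TIGK. In 100 simulations without any treatment effect r had a mean of 0.473 and 0.486 and a maximum of 0.507 and 0.523. The simulations used the spread of the joint fit, which was below that of TIGK alone. Between the lines, 609 genes changed in the same direction at -25°C (339 higher, Fisher exact one-sided p = 1.52e-132; 270 lower, Fisher exact one-sided p = 9.25e-73) and 93 in opposite directions, with 163.4 and 163.9 for independent calls. At 60°C the lines shared 1299 genes, 638 higher and 661 lower, against 319.9, and 131 went in opposite directions. The correlation across genes between the lines was 0.124 (rho 0.212) at -25°C and 0.217 (rho 0.291) at 60°C.

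**Figure D3:**
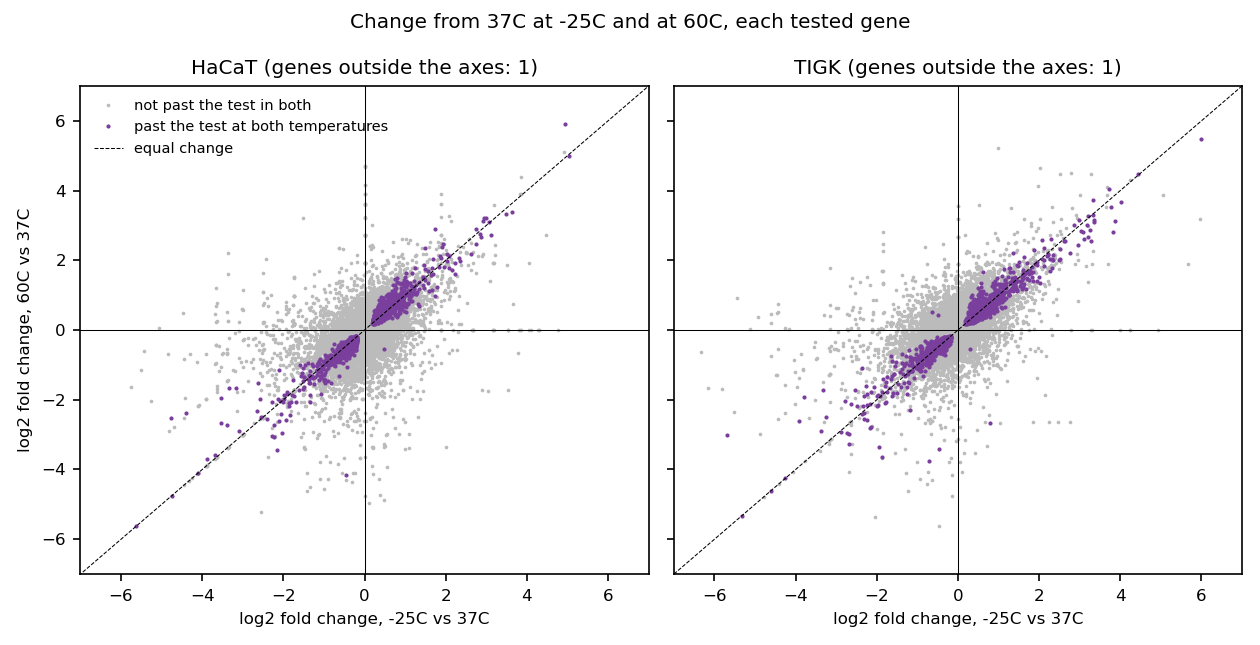
Log2 fold change of each tested gene at 60°C against that at -25°C, both relative to 37°C, in HaCaT and in TIGK, with genes past the test in both comparisons in purple and a dashed line for equal change. Of the purple genes, 1599 in HaCaT and 2083 in TIGK lie in the same direction under both treatments, and 1 and 4 in opposite directions.

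**Figure D4:**
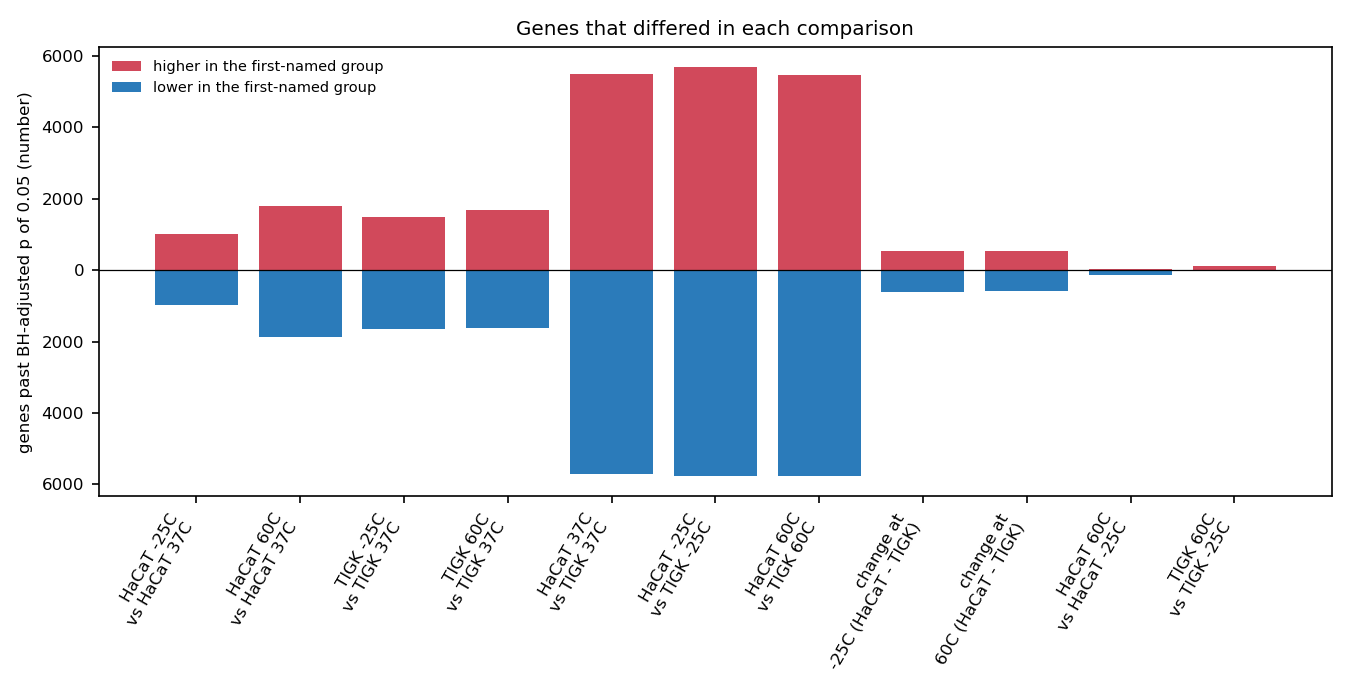
Bars give the number of genes past the test (edgeR, adjusted p under 0.05), higher and lower, in each of the 11 comparisons. The comparisons between the lines call between 11225 and 11448 genes each, those with 37°C between 1985 and 3672, and those of 60°C with -25°C 185 and 126.

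The lines were also compared with each other. At 37°C, of 26 tested HOX genes, which set position along the body, 22 were higher in HaCaT and 2 lower (23 and 2 adjusted over the list alone; adjusted p = 2.23e-08, and adjusted p = 0.00406 with an estimated correlation), HOXA9 by 5.93 ± 0.16. KRT7, a keratin of simple epithelia, was higher in HaCaT by 9.31 ± 0.14 (1023 ± 53.1 against 1.58 ± 0.458 CPM). KRT13, the keratin of lining mucosa, was lower by 5.16 ± 0.14 (53.3 ± 7.84 against 1901 ± 255 CPM). PITX1, a homeobox gene, was lower in HaCaT (log2 difference -2.08 ± 0.09). GALNT5, a glycosyltransferase gene, had 71.1 ± 0.761 CPM in HaCaT and 0 counts in TIGK, at least 1560-fold higher.

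Of 26 interferon-stimulated genes, 23 were lower in HaCaT (adjusted p = 2.56e-10, and adjusted p = 0.241 with an estimated correlation). BST2, an interferon-induced antiviral gene, was lower by 10.32 ± 0.26 and ISG15 by 2.02 ± 0.15. Oral epithelial genes were lower in 12 of 20 and higher in 2 (12 and 3 adjusted over the list alone; adjusted p = 0.0341, and adjusted p = 0.241 with an estimated correlation). Cornified-layer genes were higher in 14 of 32 and lower in 8 (adjusted p = 0.0616), FLG by 7.15 ± 0.12 and KRT1 by 4.18 ± 0.35. Sterol genes were higher in 13 of 20 and lower in 5 (adjusted p = 0.0102, adjusted p = 0.241 with an estimated correlation, and 0.0526 with only the compared libraries). Temperature-sensing channels were higher in 5 of 9 and lower in 2 (adjusted p = 0.0177, adjusted p = 0.241 with an estimated correlation, 0.0773 with only the compared libraries and 0.0734 without the doubted libraries). TRPV3, a warmth-activated channel of keratinocytes, was lower by 4.16 ± 0.33 in HaCaT and TRPV4 higher by 2.88 ± 0.21. HSPA1A was higher in HaCaT by 0.91 ± 0.09. TERT, the telomerase gene, was lower by 1.68 ± 0.23.

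Markers of other cell types also differed: fibroblast markers were lower in 5 of 7 and higher in 1 (adjusted p = 0.123), DCN, a matrix proteoglycan, by a decrease from 77.7 ± 18.7 CPM in TIGK to 0.19 ± 0.0154 in HaCaT. POSTN was higher in HaCaT, at least 205-fold, with 0 counts in TIGK. Melanocyte markers were lower in 2 of 5 (adjusted p = 0.0621), leukocyte markers in 2 of 3, and endothelial and Merkel cell markers were higher in 1 and lower in 1 of 5 (adjusted p = 0.424). KDR, an endothelial receptor gene, had 14.5 ± 1.63 CPM in TIGK and 0 counts in HaCaT, at least 354-fold lower. Replication-dependent histones were higher in 10 of 33 and lower in 1 (adjusted p = 0.306). Mesenchymal genes were higher in 8 of 18 and lower in 10 (adjusted p = 0.183; the median was negative, the mean and the test positive). The test called 11225 genes, 5506 higher in HaCaT and 5719 lower. VIM, which encodes vimentin, had 9.97 ± 1.6 CPM in HaCaT and 0 counts in TIGK, at least 217-fold higher.

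At -25°C the lines differed in 11448 genes, 5683 higher in HaCaT and 5765 lower, and at 60°C in 11243, 5475 higher and 5768 lower. FLG was higher in HaCaT by 5.53 ± 0.11 at -25°C and 5.57 ± 0.11 at 60°C. The HaCaT minus TIGK difference was -3.44 ± 0.22 and -3.88 ± 0.23 for KRT16, and -5.61 ± 0.14 and -6.40 ± 0.15 for KRT13. KRT1 was lower by 1.10 ± 0.31 in HaCaT at 60°C (29.3 ± 5.7 against 62.7 ± 7.45 CPM) and did not pass the test at -25°C (0.58 ± 0.30, adjusted p = 0.111). UCHL1, a ubiquitin hydrolase gene, had 0 counts in HaCaT at both temperatures and was at least 3670-fold and 3290-fold lower there.

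HOX genes were higher in HaCaT in 20 of 26 and lower in 2 at both temperatures (adjusted p = 4.52e-08 at -25°C and 4.99e-09 at 60°C, and adjusted p = 0.011 and 0.00264 with an estimated correlation). Interferon-stimulated genes were lower in 25 of 26 at both (adjusted p = 7.39e-10 and 4.56e-10, and adjusted p = 0.217 and 0.247 with an estimated correlation). Oral epithelial genes were lower in 12 and 15 of 20 and higher in 2 and 3 (adjusted p = 0.00191 and 0.00171, and adjusted p = 0.059 and 0.0784 with an estimated correlation). Stress response genes were higher in 15 and 16 of 24 and lower in 6 and 3 (adjusted p = 0.00352 and 0.000149, and adjusted p = 0.217 and 0.166 with an estimated correlation), and sterol genes were higher in 12 and 13 of 20 and lower in 4 and 2 (adjusted p = 0.00089 and 2.42e-05, and adjusted p = 0.217 and 0.13 with an estimated correlation). Wound genes were lower in 9 of 14 and higher in 1 at both (adjusted p = 0.0453 and 0.0472, adjusted p = 0.217 and 0.247 with an estimated correlation, 0.0541 and 0.0647 without the doubted libraries, and 0.0767 at 60°C with only the compared libraries). Channels were higher in 5 of 9 and lower in 3 at both (adjusted p = 0.0349 and 0.0273, adjusted p = 0.361 and 0.364 with an estimated correlation, 0.0564 and 0.0522 without the doubted libraries, and 0.0739 at 60°C with only the compared libraries). At 60°C mitochondrial genes were higher in 11 of 13 and antioxidant genes were higher in 10 of 25 and lower in 6 (adjusted p = 0.0257 and 0.0273, and adjusted p = 0.453 for both with an estimated correlation). Cornified-layer genes were lower in 16 of 32 at -25°C and in 21 at 60°C, and higher in 8 at both (adjusted p = 0.475 and 0.374). Adjusted over the list alone, 18 cornified-layer genes were lower at -25°C. With the same adjustment at 60°C, 6 channels were higher, and 26 interferon-stimulated genes and 3 sterol genes lower.

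The difference between the lines' changes at -25°C was tested directly, as HaCaT change minus TIGK change. The change of cornified-layer genes was lower in HaCaT than in TIGK in 15 of 32 (19 adjusted over the list alone), with a median of -1.87 (adjusted p = 2.67e-19, and adjusted p = 2.14e-05 with an estimated correlation). Against 37°C, 3 of the 32 fell and 2 rose in HaCaT, while 19 rose in TIGK. For KRT1 the difference was -3.60 ± 0.45, for SPRR1B -3.39 ± 0.38 and for FLG -1.62 ± 0.16. Wound keratins and antimicrobial genes had a lower change in 6 of 14 (7 adjusted over the list alone; median -1.34; adjusted p = 8.54e-13, and adjusted p = 0.00123 with an estimated correlation), KRT16 by a difference of -2.53 ± 0.29. Immediate early genes had a lower change in 6 of 39 and a higher one in 2 (13 and 3 adjusted over the list alone; adjusted p = 0.00413, and adjusted p = 0.221 with an estimated correlation), MYC by -1.33 ± 0.12. For HSPA1A the difference was 0.26 ± 0.13 (adjusted p = 0.279), and heat shock genes had a higher change in 3 of 28 and a lower one in 3 (adjusted p = 0.313).

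Stress response genes had a higher change in HaCaT in 5 of 24 (10 higher and 2 lower adjusted over the list alone; adjusted p = 0.001, and adjusted p = 0.159 with an estimated correlation). Lower changes were counted in 5 of 20 basal genes (adjusted p = 0.00213, and adjusted p = 0.077 with an estimated correlation), DLK2 by -0.62 ± 0.09. They were counted in 3 of 23 inflammatory genes, with 1 higher (4 and 1 adjusted over the list alone; adjusted p = 0.0121, and adjusted p = 0.0604 with an estimated correlation), S100A8, an antimicrobial calcium-binding protein, by -3.02 ± 0.37. Osmotic genes had lower changes in 4 of 11 (6 lower and 3 higher adjusted over the list alone; adjusted p = 0.0358, and adjusted p = 0.159 with an estimated correlation), AQP3 by -1.09 ± 0.14. Oral epithelial genes had lower changes in 3 of 20 and higher in 2 (6 and 2 adjusted over the list alone; adjusted p = 0.0109, adjusted p = 0.077 with an estimated correlation, and 0.0824 without the doubted libraries). Ribosomal protein genes had a median of 0.16 (adjusted p = 0.0434, adjusted p = 0.923 with an estimated correlation, 0.407 without the doubted libraries, 0.066 with only the compared libraries and 0.0778 with a term for the replicate block). Without the doubted libraries 13 of 33 cornified-layer genes, 5 wound genes and 6 inflammatory genes had lower changes, and 9 stress response genes higher ones. In all, 1170 genes differed between the lines' changes, 550 higher and 620 lower in HaCaT. The number was 713 with only the compared libraries, 730 and 779 without HaCaT 37°C replicate 3 or 2, and 2358 without TIGK 37°C replicate 3.

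At 60°C the change of cornified-layer genes was lower in HaCaT in 14 of 32 (16 adjusted over the list alone), with a median of -1.55 (adjusted p = 1.28e-23, and adjusted p = 1.13e-05 with an estimated correlation). The difference was -5.28 ± 0.47 for KRT1, -3.87 ± 0.39 for SPRR1B and -4.89 ± 0.55 for DSG1. Wound genes had lower changes in 6 of 14 (8 adjusted over the list alone; median -1.71; adjusted p = 3.76e-12, and adjusted p = 0.0014 with an estimated correlation). Stress response genes had higher changes in 9 of 24 (16 higher and 1 lower adjusted over the list alone; adjusted p = 2.11e-09, and adjusted p = 0.0137 with an estimated correlation). HSPA5 differed by 0.49 ± 0.09, with a rise in HaCaT from 1525 ± 38.3 to 2129 ± 39.6 CPM, and XBP1, a transcription factor of that response, by 0.46 ± 0.1. Osmotic genes had lower changes in 5 of 11 and a higher one in 1 (7 and 1 adjusted over the list alone; adjusted p = 7.98e-07, and adjusted p = 0.0052 with an estimated correlation), AQP3 by -1.36 ± 0.14. Inflammatory genes had lower changes in 6 of 23 (adjusted p = 0.000531, and adjusted p = 0.00905 with an estimated correlation), IL1RN, the antagonist of the interleukin 1 receptor, by -1.04 ± 0.15. Basal genes had lower changes in 5 of 20 and a higher one in 1 (11 and 1 adjusted over the list alone; adjusted p = 0.00015, and adjusted p = 0.0319 with an estimated correlation), LAMA3 by -0.52 ± 0.09. For HSPA1A the difference was 0.38 ± 0.13 (adjusted p = 0.0854), and heat shock genes had higher changes in 3 of 28 and lower in 3 (7 and 3 adjusted over the list alone; adjusted p = 0.68).

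Ribosomal protein genes had higher changes in HaCaT at 60°C in 4 of 80 (19 higher and 1 lower adjusted over the list alone; adjusted p = 3.91e-14, and adjusted p = 0.485 with an estimated correlation), and respiratory chain genes in 3 of 82 (1 adjusted over the list alone; adjusted p = 5.31e-08, and adjusted p = 0.595 with an estimated correlation). Sterol genes had higher changes in 7 of 20 (9 higher and 1 lower adjusted over the list alone; adjusted p = 0.000103, and adjusted p = 0.0886 with an estimated correlation). Oral epithelial genes had lower changes in 5 of 20 and a higher one in 1 (6 and 1 adjusted over the list alone; adjusted p = 0.0101, and adjusted p = 0.0522 with an estimated correlation), KRT13 by -1.25 ± 0.17. Mitochondrial genes had higher changes in 2 of 13 (adjusted p = 0.0477, adjusted p = 0.602 with an estimated correlation, 0.0573 with library size alone, 0.077 with only the compared libraries and 0.0769 with a term for the replicate block). In the fit that left out the doubted libraries, 11 of the 13 had higher changes (adjusted p = 4.7e-13 at the preset correlation, not repeated with an estimated one). Without the doubted libraries 15 of 33 cornified-layer genes and 7 wound genes had lower changes, as did 10 basal genes and 8 oral epithelial genes. Higher ones were then counted for 13 stress response genes, 19 ribosomal protein genes and 10 respiratory chain genes. In all, 1128 genes differed, 548 higher and 580 lower in HaCaT. The number was 2221 without the doubted libraries and 1739 without TIGK 37°C replicate 3. It was 714 and 697 without HaCaT 37°C replicate 1 or 3, 723 and 743 without HaCaT 60°C replicate 1 or 3, and 745 and 744 without TIGK 60°C replicate 1 or 2.

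**Figure D5:**
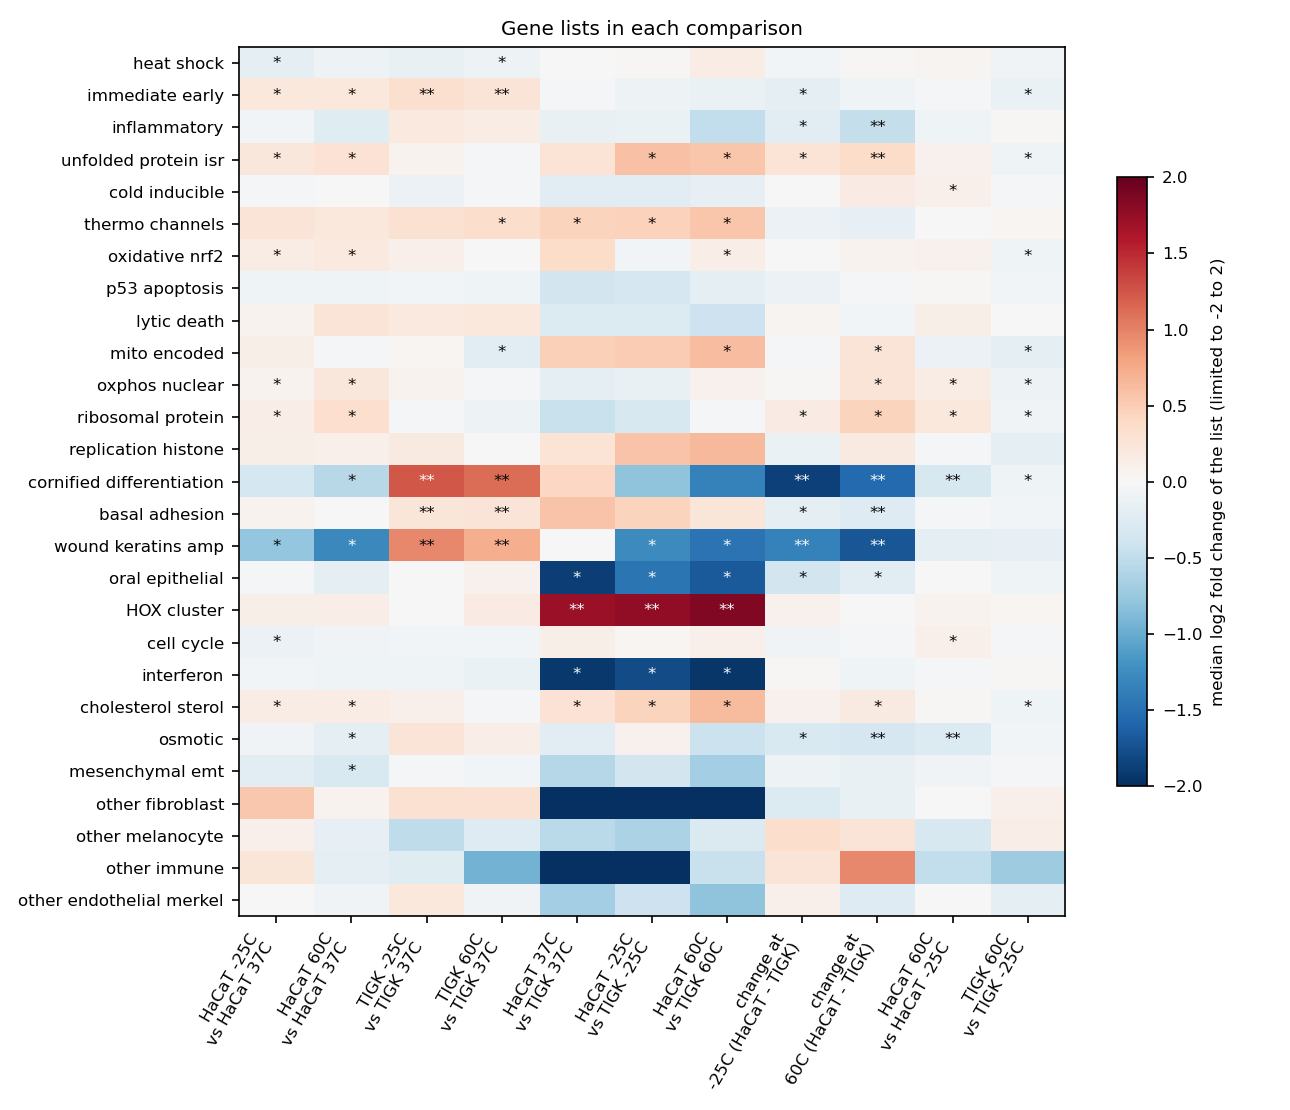
Median log2 fold change of each gene list (vertical axis) in each comparison (horizontal axis), coloured from -2 to 2, with 1 star where camera gave an adjusted p under 0.05 and 2 stars where the estimated correlation did as well. The cornified-layer list has medians of 1.25 and 1.12 in TIGK at -25°C and 60°C, -0.55 in HaCaT at 60°C, and -1.87 and -1.55 for the difference between the lines.

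The authors' deposited tables list 2756 genes for HaCaT at -25°C, 4198 for HaCaT at 60°C, 843 for TIGK at -25°C and 1172 for TIGK at 60°C. The joint fit called 62.2%, 76.1%, 99.1% and 98.3% of them in the same direction. The share for HaCaT was 73.1% and 81.9% with DESeq2 on all libraries, and 99.9% at both temperatures with only the 6 compared libraries. For HaCaT against TIGK the authors' deposited tables list 7449, 8218 and 8862 genes at 37°C, -25°C and 60°C, of which 99.8%, 98.2% and 96.4% were called in the same direction and 8, 0 and 0 genes in the opposite one. In the 37°C table the gene symbol and the Ensembl ID differed for 16 genes, and the table was joined by ID. A positive fold change in these 3 tables means a higher level in TIGK. In the authors' deposited table for 60°C a text column describes 4303 genes with negative fold changes as lower in HaCaT, while their counts are higher in HaCaT.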

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

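The tests of noise in the shared 37°C libraries, of new transcripts in genes of at most 100 kb, and of one handling difference of the 37°C libraries were chosen only after the result was seen, as were the second draws of splits at -25°C and 60°C.

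The results given here stand out because the change in HaCaT and the change in TIGK differed by a direct test (HaCaT change minus TIGK change, log2). At -25°C 1170 genes did. The median differences of the lists past their test were -1.87 for cornified-layer genes, -1.344 for wound keratins and antimicrobial genes, -0.37 for oral epithelial, -0.312 for osmotic, -0.222 for inflammatory, -0.199 for basal and -0.184 for immediate early genes, and 0.271 for stress response and 0.161 for ribosomal protein genes. Cornified-layer and wound genes passed with an estimated correlation too, and the others did not: adjusted p = 0.077 for oral epithelial, 0.159 for osmotic, 0.0604 for inflammatory, 0.077 for basal, 0.221 for immediate early, 0.159 for stress response and 0.923 for ribosomal protein genes with an estimated correlation. The genes with the largest differences were ID4 (2.927), IRAK3 (3.143), VSTM2L (3.138), KRT1 (-3.601), KRT6B (-3.927), GAL (-3.62), CDH16 (-5.136) and SLC16A9 (-3.674). The fitted values of MXRA5 (4.987) and PCDHAC2 (5.458) rest on 0 counts in TIGK at -25°C and are no bounds. IRAK3 did not pass without HaCaT 37°C replicate 2 or 3 or HaCaT -25°C replicate 2 or 3 (adjusted p 0.0607, 0.0696, 0.0639 and 0.0708). MXRA5 did not pass without TIGK 37°C replicate 1 or 2 or TIGK -25°C replicate 1 or 2 (adjusted p 0.0797, 0.0554, 0.0673 and 0.081), or with only the compared libraries (0.0529). VSTM2L did not pass without HaCaT 37°C replicate 1, 2 or 3, HaCaT -25°C replicate 2 or TIGK -25°C replicate 2 (adjusted p 0.0551, 0.0753, 0.0881, 0.333 and 0.0562). SLC16A9 did not pass without TIGK 37°C replicate 2 or TIGK -25°C replicate 1 or 2 (adjusted p 0.0695, 0.0544 and 0.0847), or without the doubted libraries (0.108).

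At 60°C 1128 genes differed. The median differences of the lists were -1.554 for cornified-layer genes, -1.708 for wound keratins and antimicrobial genes, -0.472 for inflammatory, -0.336 for osmotic, -0.265 for basal and -0.219 for oral epithelial genes, and 0.447 for ribosomal protein, 0.371 for stress response, 0.263 for respiratory chain, 0.25 for mitochondrial and 0.183 for sterol genes. Of these lists 5 did not pass with an estimated correlation: adjusted p = 0.0522 for oral epithelial, 0.485 for ribosomal protein, 0.595 for respiratory chain, 0.602 for mitochondrial and 0.0886 for sterol genes with an estimated correlation. The genes with the largest differences were AGR2 (2.878), COL4A4 (2.978), VSTM2L (3.074), KRT1 (-5.277), DSG1 (-4.89), KRT6B (-4.884), SPRR1B (-3.874) and SPRR1A (-3.58). The fitted values of MXRA5 (4.751) and PCDHAC2 (5.212) again rest on 0 counts in TIGK at 60°C. MXRA5 did not pass without TIGK 37°C replicate 1 or 2 or TIGK 60°C replicate 1, 2 or 3 (adjusted p 0.0836, 0.0566, 0.075, 0.0758 and 0.066), or with only the compared libraries (0.0565). VSTM2L did not pass without HaCaT 37°C replicate 1, 2 or 3 (adjusted p 0.0843, 0.102 and 0.12) or HaCaT 60°C replicate 1 or 3 (0.793 and 0.052). Nor did VSTM2L pass without TIGK 37°C replicate 2 (0.0555), without TIGK 60°C replicate 1, 2 or 3 (0.0786, 0.0622 and 0.0765), with library size alone (0.0537), with only the compared libraries (0.0679) or with a term for the replicate block (0.0697).

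The changes of cornified-layer genes differed between the lines: of 32, 10 fell in HaCaT at 60°C (adjusted p = 0.000603, and adjusted p = 0.0635 with an estimated correlation), 3 fell and 2 rose there at -25°C (adjusted p = 0.27), and 19 rose in TIGK at each temperature. The tables argue against 1 library as the cause, since in each fit without 1 library at least 11 members had a lower change in HaCaT (11 to 16), and against a scaling difference, since with library size alone the median difference of all tested genes was 0.022 at -25°C and -0.043 at 60°C while that of the list stayed at -1.852 and -1.577. What stays open is a different culture state of the 37°C libraries, such as their density when lysed: the range of the list's mean among 37°C replicates was 0.278 in HaCaT, where treated libraries differed by -0.452 from 37°C (ratio 0.614), and 0.223 in TIGK, where they differed by 1.257. The labels do not describe the cultures, so such a state may contribute and cannot be told apart from the treatment. A response of each line to temperature is the biological explanation that the design names, and it is a hypothesis here.

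The same genes changed at -25°C and at 60°C, 1599 in the same direction in HaCaT and 2083 in TIGK. Simulations without any treatment effect gave 31.6% of the observed covariance across genes in HaCaT and 28.1% in TIGK. They used the joint spread of 10.8%. For HaCaT, whose own spread was 6.37%, this argues against noise of the shared 37°C libraries as the whole cause. The own spread of TIGK was 13.6%, and its 37°C replicate 3 stood apart, which the simulations did not copy. The TIGK share is thus likely too low and does not settle the question there. Without the doubted libraries 2251 genes were still shared in TIGK. New transcripts made during the 10 minutes stay open for the genes higher under both treatments. Their test covers rises only and says nothing on the 759 and 1068 genes lower under both treatments in HaCaT and TIGK. Whether RNA can be lost within 10 minutes to the extent seen for FN1 in both lines was not tested. A difference of the 37°C libraries thus stays open for these falls too. Genes longer than 100 kb are more than a polymerase at 10 kb per minute (an assumed speed) would cover. They were 10.4% (87 of 840, 95% interval 8.4% to 12.6%) of the higher genes in HaCaT and 12.5% (127 of 1015, 10.5% to 14.7%) in TIGK. Of the genes tested they were 15.9%, a deficit that goes with new transcripts. However, 13 of the 87 and 32 of the 127 were at least 2-fold higher under both treatments, which goes against new transcripts at that speed. The share met the bound set beforehand against new transcripts, at least 0.5 times that of the genes tested, but that bound and these genes exclude nothing, since both rest on a speed that no table measures; for the 753 and 888 shorter genes no value decides. One handling difference of all 37°C libraries cannot be told apart from a response common to both temperatures, since each comparison uses the same 37°C libraries. The r across genes between the lines' changes was 0.124 at -25°C and 0.217 at 60°C, or 0.083 and 0.19 without the doubted libraries. These values lay above 0 but short of the 0.5 at each temperature that such a difference as the cause was taken to give. That r runs over all genes tested, called or not. Of genes called in both lines, 609 changed in the same direction and 93 in opposite ones at -25°C, and 1299 and 131 at 60°C. A handling difference may contribute, as may new transcripts or a true response to leaving 37°C.

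The libraries were also divided in other ways to see how many genes such splits give. In a comparison of 3 with 3 libraries the real split is 1 of 10, too few for a share under 0.05. Each other split mixes libraries of both groups, so the real difference enters the spread and lowers the number of genes. These low numbers therefore do not show what data without a difference would give. The real numbers and the highest of the other splits were 1985 and 1 for HaCaT at -25°C, 3672 and 0 at 60°C, 3139 and 590 for TIGK at -25°C, and 3318 and 0 at 60°C. They were 11225 and 3 for the lines at 37°C, 11448 and 0 at -25°C, 11243 and 0 at 60°C, 185 and 0 for 60°C against -25°C in HaCaT, and 126 and 0 in TIGK. For the difference between the lines at -25°C, 100 splits were drawn. The real one alone, 1 of 100, gave as many as 1170 genes (highest other 1132), and a second draw from the 200 possible splits gave the same numbers. The split with 1132 kept the HaCaT groups, so it holds the real change of HaCaT, and left 2 of 6 TIGK libraries in their own group. The split that exchanges the TIGK groups was in neither draw, so whether chance can be excluded is not settled by these splits.

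For the difference at 60°C, 7 of 100 splits, the real one included, gave as many as 1128 genes. All 6 others kept the HaCaT groups and so hold the real change of HaCaT. The highest of them gave 4972 genes, several times the real number, which points to a structure of the samples: that split exchanged the TIGK groups at 37°C and 60°C, so it measures the sum of the lines' changes. In a second draw, 4 of 100 splits gave as many (highest other 1887). The result thus depends on which splits are drawn, and chance is not excluded by them.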

How the results depend on the processing

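The settings without the doubted libraries and with DESeq2 on only the compared libraries were chosen after seeing the data, as were both comparisons of 60°C with -25°C and their tests. Where a value moved, the cause was not tested unless it is named. With the depth, number and joint spread of these libraries, 58% of genes above 1 CPM simulated as 1.5-fold changed in HaCaT 60°C were called. What each of these contributes was not separated.

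Of 991 named calls, 991 held with relative log expression factors, 980 with library size alone, 990 with DESeq2, 967 without the filter, and 987 with protein-coding genes only. With the stricter filter 989 of 989 held, with only the compared libraries 890 of 986, without the doubted libraries 965 of 989, and with DESeq2 on only the compared libraries 752 of 805. The fits without 1 library kept 6229 of 6804 and the replicate block kept 947 of 991. A log2 change of at least 1 kept 562, since it removes small changes by construction. None of these named calls changed direction in any of the settings.

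With only the compared libraries the number of genes was 4252 (HaCaT -25°C), 6158 (HaCaT 60°C), 886 (TIGK -25°C), 1294 (TIGK 60°C), 713 (difference between the lines at -25°C), and 1659 and 255 (60°C against -25°C in HaCaT and TIGK). Without the doubted libraries it was 3201, 5786, 2221 (difference at 60°C), 901 and 353 for HaCaT -25°C, HaCaT 60°C, that difference, and 60°C against -25°C in HaCaT and TIGK. With DESeq2 on only the compared libraries it was 3615 (HaCaT -25°C), 1182 and 1682 (TIGK -25°C and 60°C). For 60°C against -25°C, DESeq2 on all libraries gave 438 and 246, no filter 305 and 346, protein-coding genes only 70 in TIGK, and the replicate block 113 in HaCaT. With a log2 change of at least 1 as well, the numbers were 274, 453, 392 and 496 for the treatments, 5184, 5379 and 5235 for the lines, 296 and 286 for the differences, and 32 and 36 for 60°C against -25°C. The other settings gave numbers within 1.5 times.

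Leaving out 1 library at a time gave 1108 to 1428 genes for HaCaT -25°C, 2473 to 2784 for HaCaT 60°C, 2111 to 3718 for TIGK -25°C, 2290 to 3589 for TIGK 60°C, 10379 to 11427, 10699 to 11072 and 10511 to 10570 for the lines at 37°C, -25°C and 60°C, 730 to 2358 and 697 to 1739 for the differences at -25°C and 60°C, and 11 to 72 and 60 to 238 for 60°C against -25°C in HaCaT and TIGK. HaCaT -25°C gave 1243, 1108 and 1242 without 37°C replicate 1, 2 or 3, and 1166 and 1282 without -25°C replicate 1 or 3. The difference at -25°C gave 730 and 779 without HaCaT 37°C replicate 3 or 2 and 2358 without TIGK 37°C replicate 3. The difference at 60°C gave 714 and 697 without HaCaT 37°C replicate 1 or 3, 723 and 743 without HaCaT 60°C replicate 1 or 3, 745 and 744 without TIGK 60°C replicate 1 or 2, and 1739 without TIGK 37°C replicate 3. HaCaT 60°C against -25°C gave 63, 35 and 63 without -25°C replicate 1, 2 or 3 and 11, 36 and 72 without 60°C replicate 1, 2 or 3. TIGK gave 71, 67 and 238 without -25°C replicate 1, 2 or 3 and 72, 77 and 60 without 60°C replicate 1, 2 or 3.

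Of 234 list tests in the 9 comparisons, 71 passed with the preset correlation and 19 with an estimated one, the same direction in each. With library size alone 71 passed (70 of them also passed with the preset in the same direction), with the replicate block 72 (67), with only the compared libraries 71 of 220 (62), and without the doubted libraries 78 (62). Ribosomal protein genes at 60°C against -25°C in TIGK went from lower to higher without the doubted libraries (adjusted p = 0.783, against 0.00714 with all; 0.888 with an estimated correlation).

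Of the overlaps, a log2 change of at least 1 left 33 and 75 genes shared between the lines at -25°C and 60°C, and 174 and 230 shared between the treatments in HaCaT and TIGK, fewer by construction. Without the doubted libraries 2044 genes were shared between the lines at 60°C and 2625 between the treatments in HaCaT. Genes with opposite directions between the lines then rose too, from 93 to 157 at -25°C and from 131 to 250 at 60°C. The correlation across genes between the lines at -25°C was 0.188 with DESeq2. The share of the authors' genes called in the same direction was 73.1% (HaCaT -25°C), 81.9% (HaCaT 60°C) and 95.5% (lines at 60°C) with DESeq2. With only the compared libraries it was 99.9% for HaCaT at both temperatures, 94.4% and 94.7% for TIGK, and 99.8% for the lines at -25°C and at 60°C. With DESeq2 on only those it was 99.4% and 100% for HaCaT, 99.5% for the lines at 37°C and 100% at -25°C and 60°C.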

Other observations

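Both comparisons of 60°C with -25°C, with their list tests and settings, were chosen only after the data were seen. Compared directly in the joint fit, 60°C and -25°C differed in few genes in either line. The biological coefficient of variation of that fit (10.8%) was above that of HaCaT fitted alone (6.37%). The number ran from 11 to 1659 in HaCaT and from 60 to 353 in TIGK over the settings given below. A small number thus does not show near equality in either line. In HaCaT 185 genes differed, 45 higher at 60°C and 140 lower. KRT13 was lower at 60°C by 0.83 ± 0.12 (SE, n = 3 in each group; adjusted p = 0.00354), and GABRE, a subunit of the GABA-A receptor, by 1.03 ± 0.13, from 98.8 ± 6.32 to 48.2 ± 1.73 CPM. KRT1 was lower by 2.07 ± 0.31, from 122.5 ± 39.2 to 29.3 ± 5.7 CPM (adjusted p = 0.00947, and 0.0663, 0.0567 and 0.0529 without HaCaT 60°C replicate 1, 2 or 3). Of 32 cornified-layer genes 3 were lower (8 adjusted over the list alone; median -0.32; adjusted p = 4.46e-05, and adjusted p = 0.00931 with an estimated correlation). Of 11 osmotic stress genes 2 were lower (7 adjusted over the list alone; median -0.27; adjusted p = 3.87e-07, and adjusted p = 0.00931 with an estimated correlation). Ribosomal protein and respiratory chain genes were higher as lists, with 0 of 80 and 1 of 82 past the edgeR test (7 of the ribosomal protein genes higher and 2 lower at an unadjusted p under 0.05, and 0 called by DESeq2; adjusted p = 1.53e-09 and 2.07e-08, and adjusted p = 0.722 for both with an estimated correlation). Leaving out the doubted libraries gave 6 of 33 cornified-layer genes and 5 osmotic genes lower, and 11 ribosomal protein genes higher. Of 9 cold-inducible genes 1, CIRBP, was higher at 60°C (3 adjusted over the list alone; adjusted p = 0.0315, and adjusted p = 0.173 with an estimated correlation). CIRBP rose by 0.29 ± 0.07, with adjusted p = 0.0316, 0.0605 with the replicate block, and 0.137, 0.143, 0.0797, 0.249, 0.063 and 0.0529 without HaCaT -25°C replicates 1 to 3 and 60°C replicates 1 to 3 in turn. The number 185 fell to 63, 35 and 63 without HaCaT -25°C replicate 1, 2 or 3 and to 11, 36 and 72 without 60°C replicate 1, 2 or 3. The 45 higher genes became 12, 5 and 12, and 3, 10 and 13, in the same fits. The number 185 was 1659 with only the compared libraries, 901 without the doubted libraries, 438 with DESeq2, 305 without the filter and 113 with the replicate block.

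In TIGK 126 genes differed between 60°C and -25°C, 108 higher at 60°C and 18 lower. HSF4, a heat shock transcription factor, was higher at 60°C (13.5 ± 1.28 against 5.91 ± 0.486 CPM, adjusted p = 0.000105). In HaCaT HSF4 was higher by 0.71 ± 0.15 (13.8 ± 0.251 against 8.45 ± 0.778 CPM, adjusted p = 0.0176). There HSF4 had adjusted p = 0.11 and 0.0797 without HaCaT -25°C replicate 2 or 3 and 0.0981, 0.0615 and 0.07 without 60°C replicate 1, 2 or 3. PGGHG, a glycosidase gene, was higher in TIGK at 60°C (58.0 ± 2.69 against 25.3 ± 1.95 CPM), and CCDC18 by 1.17 ± 0.16. MT-ND3, a mitochondrial subunit of the respiratory chain, was lower by 0.68 ± 0.1 (adjusted p = 0.000602, and 0.051 without the doubted libraries). Of 13 mitochondrial genes 1 was lower (2 adjusted over the list alone, adjusted p = 6.84e-07, and adjusted p = 0.458 with an estimated correlation). Without the doubted libraries 9 were lower (adjusted p = 1.16e-31 at the preset correlation, not repeated with an estimated one). Another 7 lists lay lower at 60°C with 0 members past the edgeR test: immediate early and respiratory chain genes (adjusted p = 0.000923 for both), sterol (0.0068), ribosomal protein (0.00714), stress response (0.0172), cornified-layer (0.0247) and antioxidant genes (0.0465). In that order they had adjusted p = 0.458, 0.842, 0.458, 0.888, 0.458, 0.447 and 0.73 with an estimated correlation. At an unadjusted p under 0.05, 8 of 39, 6 of 82, 4 of 20, 2 of 80, 3 of 24, 3 of 32 and 3 of 25 were lower, with 1 respiratory chain and 1 antioxidant gene higher, and DESeq2 called 1 immediate early and 2 sterol genes lower. When the doubted libraries were left out, adjusted p was 0.481 for respiratory chain and 0.787 for antioxidant genes, and ribosomal protein genes lay higher (0.783). The antioxidant list also had 0.0524 with library size alone, 0.0567 with the replicate block and 0.068 with only the compared libraries. The number 126 became 71, 67 and 238 without TIGK -25°C replicate 1, 2 or 3 and 72, 77 and 60 without 60°C replicate 1, 2 or 3. It was 255 with only the compared libraries, 353 without the doubted libraries, 246 with DESeq2, 346 without the filter and 70 with protein-coding genes only.

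Genes called between 60°C and -25°C overlapped between the lines: of the 45 higher at 60°C in HaCaT, 39 lay above 0 in TIGK (median 0.39) and 21 were also called, against 0.255 for independent calls (Fisher exact one-sided p = 2.9e-36). GC content, length and abundance are argued against, since matched genes (20 for each of 44) had a median of 0.013 in TIGK. Transcripts that run on from a close upstream gene had the value they need: 26.7% (12 of 45; 14.6% to 41.9%) had a tested gene ending within 5 kb upstream on the same strand, against 12.8% of tested genes, although a location in gene-dense regions would give the same. The 33 genes without such a neighbour had a median of 0.34 in TIGK, against 0.55 for those with one, which meets the bound set beforehand, at least 0.5 times, but not by more than its spread (the median without minus 0.5 times the median with a neighbour had a 95% range from -0.171 to 0.276), so run-on stays open for them too. Of the 140 genes lower at 60°C in HaCaT, 99 lay below 0 in TIGK (median -0.05) and 9 were among the 18 called lower there, against 0.132 for independent calls (Fisher exact one-sided p = 2.23e-15).

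The number of genes with exactly 1 count had group means of 2724 ± 559, 1687 ± 556 and 2176 ± 153 (SD, n = 3) in HaCaT at 37°C, -25°C and 60°C, and of 2701 ± 210, 1823 ± 790 and 2040 ± 104 in TIGK. The share of counts on the mitochondrial genome was 7.86%, 8.599% and 8.70% in HaCaT and 5.07%, 4.97% and 4.26% in TIGK in the same order.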
